A study of Homo sapiens with 3 samples.

How the data were processed

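RNA sequencing libraries of MCF-7 cells were compared between siRNA against the long non-coding RNA LOL (siLOL, 2 libraries) and a non-targeting siRNA (siNC, 1 library). The labels do not say whether siLOL 1 and siLOL 2 are different siRNAs or separate cultures, so they formed one group, and p-values measure only the spread between these libraries. The table's columns were matched to the samples by their names, with the column named for the control taken as siNC and the numbered pair as siLOL 1 and siLOL 2. This match is an inference: the numbered columns are named M_14_1 and M_14_2, and the 14 stands in no sample label. Reads had been aligned with HISAT2 to GRCh38, per the submitters' processing notes, which name neither a counter nor a normalization.

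The deposited values are a signal per gene made by the authors. The values are reads divided by gene length and by a factor per library, with 1 added to every gene. This was tested on the table: the least value was exactly 1, and with 1 taken off, values times the merged exon length of GENCODE v29 fell on whole multiples of 1 constant per library. Of 15130 genes with a length and values above the floor, 9559 (63.2%) were whole in all 3 libraries within 0.02 of a read, where chance gives 0.0064%. The value of 1 read in 1 kb was 1.08 in siNC, 1.02 in siLOL 1 and 0.809 in siLOL 2. The plan had assumed a value scaled to the library's reads. The authors' factor is not stated, and relative to siNC it differed from the total of recovered reads by 1.12 in both siLOL libraries.

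The added 1 was subtracted, and log2 of the value plus a pseudocount of 1 was used. Genes with a mean of at least 1 over the libraries were tested (12728 genes). Of the 18944 gene names, 18436 matched a GENCODE v29 gene by name, 436 matched by an older symbol and 72 had no match. Names turned into dates (27) were kept in the tests and left out of the named genes. No name LOL was found, so the gene was not analysed here. The strand of the libraries is not given, so reads of overlapping genes cannot be separated.

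Genes were compared by limma-trend (limma 3.58.1, R 4.3.3) with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05, two-sided. The fit had 1 residual degree of freedom and 5.78 prior degrees of freedom, and the lone siNC library was assumed to vary like the siLOL pair. The fit was tried on simulated genes, drawn independently with 1 robust spread of the siLOL pair per expression level, and with changes planted only in well-expressed genes. There it recovered 93.2% of 4-fold and 25.6% of 2-fold changes, with a mean of 124.6 calls, of which 5.6 were false. Camera called 5 of 5 moved lists and 0 unmoved ones. The simulation left out correlation between genes and differences in spread among genes of like level, so these rates need not hold for the data. The counts of genes at least 2-fold apart in both siLOL libraries were set beside 100 simulations in which both share 1 control without an effect. These gave the control the spread of the siLOL pair and drew genes independently.

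Lists of genes (32) were fixed before the data were examined, and 31 had at least 5 measured members. Each was tested with camera at a preset correlation of 0.01 and with an estimated correlation, with adjustment over the lists. The rotation test fry was run on each list too, without adjustment. Members were counted over all genes and adjusted over the list alone. The lists covered hormone response and lineage (estrogen-induced, estrogen-repressed, luminal, basal and mesenchymal, tamoxifen), growth (ribosome biogenesis, cytosolic ribosome, G1/S, G2/M, PI3K and insulin, immediate early, TGF-β), stress and death (p53, apoptosis, heat shock, endoplasmic reticulum stress, ATF4, hypoxia and glycolysis, interferon, NF-κB), metabolism (fatty acid, cholesterol, respiratory chain, mitochondrially encoded, housekeeping), small RNAs (let-7 targets, small RNA machinery), library type (histones, small nuclear and nucleolar RNAs) and other cells (fibroblast, endothelial, leukocyte).

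Named genes followed a rule fixed with the lists. They were LOL, the 12 genes highest and 12 lowest in both siLOL libraries by the smaller log2 difference (at least 5 in the higher group), up to 4 members per list with the largest such difference (at least 1 in either group), and ESR1, GATA3, FOXA1, TFF1, PGR, GREB1, MYC, CCND1, HMGA2, LIN28B, CDKN1A and MKI67. Pseudogenes and small RNAs were skipped. Genes outside this rule are described as chosen after their values were seen. Errors are the SD of the 2 siLOL libraries or the SE from limma, and siNC has no replicate. Adjusted p of the named genes ran from 0.549 to 0.971. Read ratios with 95% exact (Clopper-Pearson) intervals are given for genes whose recovered reads were whole, and a gene without reads was set against a floor of 3 reads where the exact lower limit of its ratio was above 1.

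The 3' UTRs of GENCODE v29 transcripts (at least 50 bases) were searched for every word of 7 bases, and the fold changes of genes with and without each word were compared as a z over 9875 genes with a mean of at least 10, with 100 shuffles. The pair of words with the lowest z in each siLOL library are called siLOL 1 words (GTGGTGA and its neighbour TGGTGAA) and siLOL 2 words (ACTACCT and its neighbour CTACCTA). The pair with the highest z in both (TCGGAGA and its neighbour CGGAGAA) are called siNC words. The names mark libraries only, since the words were taken from the fold changes and no siRNA sequence was at hand to compare. A planted word was found first in 20 of 20 simulated trials. Words were scored with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, intervals came from scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

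The alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.5, no low-value filter and a mean of at least 5, centring on the median, TMM-like factors, fold thresholds of 1.5 and 4, and leaving out each siLOL library. Scaling to total recovered reads, voom on recovered reads (7841 genes whole in all libraries, at least 10 reads) and a fit to word-free genes were added after the data were seen. Word-free genes are those whose 3' UTR was searched and holds none of the 6 words, so genes without a searched 3' UTR were left out of that fit as well. They can still hold related words outside the 6, such as TGGTGAT and CTACCTT. The 3' UTR of 1 transcript per gene was searched, so other transcripts can hold the words too.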

Results

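RNA sequencing of total RNA was applied to MCF-7, an estrogen receptor-positive line of luminal breast cancer. The cells had received siRNA against LOL, a long non-coding RNA (siLOL, 2 libraries), or a non-targeting siRNA (siNC, 1 library), and had spent 2 days in conditioned medium. The table held 18944 genes, of which 18653 matched protein-coding genes. The reads recovered from its values numbered 7899870 in siNC, 7451390 in siLOL 1 and 9408240 in siLOL 2. A gene of 1 kb with 3 reads had a value of 3.25 in siNC, 3.07 in siLOL 1 and 2.43 in siLOL 2, and 5008, 4588 and 4573 genes had no reads. Mitochondrially encoded genes took 5.76%, 5.53% and 5.82% of the reads in the same order, and the 10 most abundant genes took 9.09%, 7.45% and 7.46%. No gene of the table bore the name LOL, so its level was not analysed here.

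The comparison of siLOL with siNC asked which genes differ in expression after LOL knockdown. Genes of ribosome biogenesis, of the G1/S transition and induced by estrogen were lower as groups in the siLOL libraries, and p53 target genes were higher as a group. These calls came from camera with a preset correlation. With an estimated correlation each gave adjusted p = 0.726, but that test rests on 1 residual degree of freedom and could hardly pass. Fry, a rotation test on a list's own genes, gave unadjusted p = 0.0413 for ribosome biogenesis. For the G1/S, estrogen-induced and p53 lists fry gave unadjusted p = 0.290, 0.130 and 0.294. TFF1, a secreted trefoil peptide induced by estrogen (GRCh38 chromosome 21, 42362282 to 42366594), had a value of 9263 in siNC and 2990 ± 1140 (SD, n = 2) in siLOL. GREB1, a cofactor of the estrogen receptor (chromosome 2, 11482341 to 11642788), had 138 in siNC and 50.6 ± 1.74 in siLOL. PERP, a p53 target of epithelial junctions (chromosome 6, 138088505 to 138107511), had 54.8 in siNC and 184 ± 57.9 in siLOL. The estrogen receptor gene ESR1 had 178 and 102 ± 17.2, and its 3' UTR holds the 7-base words whose genes stood lowest in each siLOL library. These words are described with the comparison of siLOL 1 and siLOL 2.

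No gene passed the limma test over all 12728 genes at an adjusted p under 0.05, the smallest being adjusted p = 0.549. At an unadjusted p under 0.05 there were 1111 genes, 579 higher and 532 lower, where chance gives 636.4. With total recovered reads the split was 908 higher and 264 lower. By voom on 7841 genes 0 passed, with 638 at an unadjusted p under 0.05 (466 higher, 172 lower) where chance gives 392.05. Genes at least 2-fold higher in both siLOL libraries numbered 337, and 155 were at least 2-fold lower in both. Libraries simulated without an effect, sharing 1 control with the spread of the siLOL pair, gave a mean of 128.46 higher (range 101 to 169) and 127.56 lower (105 to 152). A siNC library of larger spread would give more such genes without an effect, so these counts do not show a shared effect. The share of higher genes followed the scaling, from 68.5% with the authors' factors to 84.7% (536 higher, 97 lower) with total recovered reads, which shifted the median log2 difference of all genes by 0.16. List medians are therefore given relative to that of all genes, and pairs marked by library are those of siLOL 1 and siLOL 2. In siLOL 1 alone 764 genes were at least 2-fold higher and 671 lower, and in siLOL 2 alone 686 and 597.

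Of the 12 genes furthest below siNC in both siLOL libraries, TSKU, a secreted leucine-rich proteoglycan (chromosome 11, 76782251 to 76798154), was the most abundant, with 1075 in siNC and 273 ± 23.0 in siLOL (log2 difference −1.97 ± 0.27 SE, adjusted p = 0.549). SLC26A2, a sulfate transporter, had 204 and 39.5 ± 27.6, and SLC25A22, a mitochondrial glutamate carrier, had 193 and 52.7 ± 2.12. POLR3G, a subunit of RNA polymerase III, had 80.0 and 14.8 ± 6.11. SPINK4 had 58.0 and 9.32 ± 4.32, and PRSS23, a serine protease, had 34.5 and 8.26 ± 0.814. NXPE3 had 23.5 and 5.68 ± 0.0634. HES7, a repressor of the somite clock, had 21.4 and 2.63 ± 2.49, while APOA1, the main protein of high-density lipoprotein, had 19.8 and 2.14 ± 0.993. PCP4 had 14.7 and 2.39 ± 0.761, the dopamine receptor gene DRD2 had 12.1 and 1.95 ± 0.298, and TUBB2B had 8.88 and 1.49 ± 0.537. The 3' UTRs of NXPE3 and PRSS23 hold a siLOL 1 word, those of NXPE3, POLR3G and SLC25A22 hold a siLOL 2 word, and that of PRSS23 also holds a siNC word.

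At the upper end, 10 of the 12 genes named had at most 4 reads in siNC. The exceptions were MYO15B, with 5.98 in siNC and 35.0 ± 1.92 in siLOL, and NHLRC1, a ubiquitin ligase gene, with 5.58 and 33.2 ± 5.59. PPARG, the nuclear receptor of fat cell differentiation, had 1.07 and 13.4 ± 9.33, from about 4, 89 and 38 reads in siNC, siLOL 1 and siLOL 2. APOBR had 1.14 and 9.98 ± 0.371. From 1 or 2 reads in siNC, TMEM31 had a read ratio of 12.1 (95% exact interval 2.01 to 494) and PRTFDC1 of 12.9 (3.43 to 109). AMPD1 had 0.434 in siNC and 6.12 ± 1.78 in siLOL, from about 1, 22 and 19 reads that were not whole, so no interval is given. With no reads in siNC, and 3 reads taken as its floor, the siLOL means of WBSCR28 and CCER2 were 3.88 and 2.54 times that floor. The exact lower limits of their read ratios were smaller, at 2.96 and 1.84. SYCE3 (6 and 3 reads in siLOL 1 and siLOL 2), SPINK8 (about 6 and 2) and TOMM20L (4 and 4) also had no reads in siNC, but the exact lower limits of their read ratios (reads rounded for SPINK8) were 0.824, 0.713 and 0.713, so a difference was not detectable at this depth. None of the 8 genes whose 3' UTR was searched holds a siLOL word. These intervals and limits cover counting error only, and not the choice of these genes by the size of their difference.

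**Figure D1:**
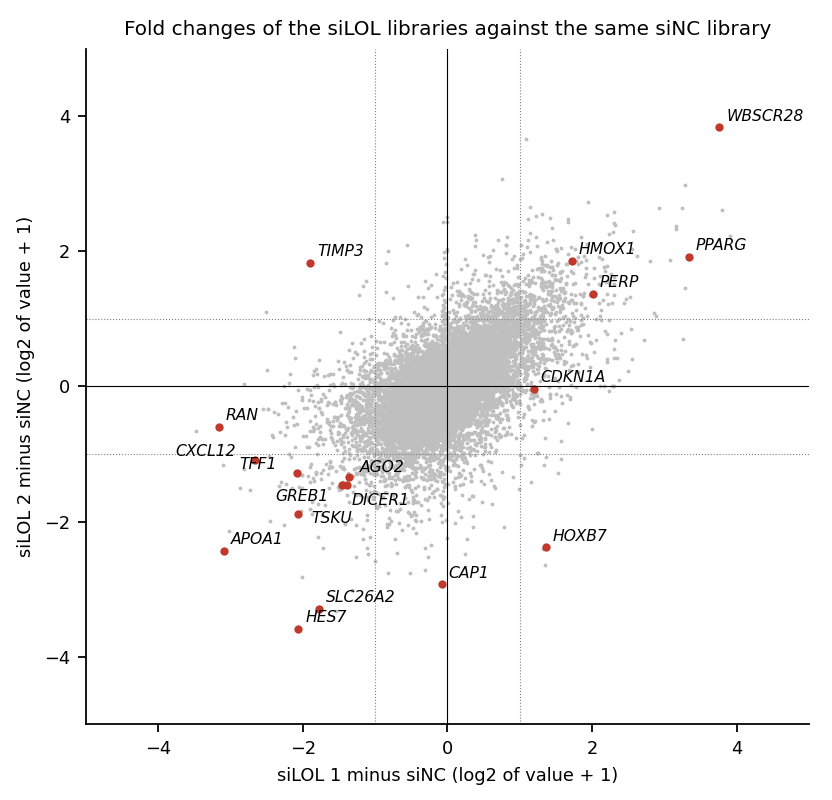
Log2 differences of siLOL 1 (horizontal axis) and siLOL 2 (vertical axis) from the siNC library, on log2 of the value plus 1, with 1 grey point per gene and named genes in red. The dotted lines mark 2-fold, beyond which 337 genes lie in both libraries at the upper right and 155 at the lower left.

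The estrogen-induced list lay at a median of −0.60 relative to all genes (log2, −0.58 in siLOL 1 and −0.47 in siLOL 2), and 23 of its 32 members were lower in both siLOL libraries against 2 higher in both. It passed camera at adjusted p = 1.11e-05, with adjusted p = 0.726 with an estimated correlation. Besides TFF1 and GREB1 (log2 differences −1.69 ± 0.38 and −1.43 ± 0.31), the members named were CXCL12, a chemokine (254 in siNC, 79.0 ± 55.9 in siLOL), and XBP1, a transcription factor of secretory cells (4094 and 1963 ± 261). No member passed over all genes, and 0 passed adjusted over the list alone. The 3' UTR of GREB1 holds a siNC word. Estrogen-repressed genes were higher as a group (median 0.38 of the mean differences, 0.21 in siLOL 1 and 0.12 in siLOL 2, 12 of 28 members higher in both and 6 lower in both, camera adjusted p = 0.0138, adjusted p = 0.726 with an estimated correlation). Adjusted over the list alone, 2 of them passed: BCAS1 (11.0 and 42.9 ± 2.19) and CYP1B1, a cytochrome that hydroxylates estradiol (92.8 and 256 ± 24.7), whose 3' UTR holds a siNC word. ERBB4 had 15.9 and 34.9 ± 3.26, and KRT4 had 2.94 and 0.521 ± 0.30. The estrogen-repressed call was lost without the low-value filter (adjusted p = 0.0840) and by voom (adjusted p = 0.467), and in both settings 0 members passed adjusted over the list alone.

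Luminal lineage genes were lower as a group, at a median of −0.30 (by library −0.32 and −0.30), with 12 of 19 members lower in both siLOL libraries and 5 higher in both (10 and 7 with total recovered reads). The list passed camera at adjusted p = 0.0138, and gave adjusted p = 0.726 with an estimated correlation. Adjusted over the list alone, 4 members passed: TFF1, XBP1, the prolactin receptor gene PRLR (157 and 72.8 ± 6.24) and the keratin gene KRT18 (15989 and 7640 ± 971). The member calls fell to 0 without the low-value filter (smallest list-adjusted p 0.194), at a mean of at least 5 (0.0502), with median centring (0.0843), TMM-like factors (0.0510) or total recovered reads (0.0947), and by voom (0.0668). The list shares TFF1, TFF3 and XBP1 with the estrogen-induced list. The 3' UTR of PRLR holds both siLOL words, and KRT18 has pseudogene copies whose reads cannot be separated in the table. The lineage factors GATA3 (2563 and 2953 ± 506) and FOXA1 (809 and 905 ± 121) had log2 differences of 0.19 ± 0.29 and 0.16 ± 0.28. PGR, the progesterone receptor gene, had 1.63 and 0.783 ± 0.539. Basal and mesenchymal genes were higher as a group (median 0.35, 0.44 in siLOL 1 and 0.18 in siLOL 2, 7 of 13 members higher in both and 1 lower, camera adjusted p = 0.0488, adjusted p = 0.815 with an estimated correlation), and 0 passed adjusted over the list alone. Among them were ACTA2 (2.86 and 11.7 ± 5.95), CAV1 (1.59 and 4.20 ± 1.17) and ITGB4 (68.7 and 97.5 ± 10.4), while SPARC had 5.38 and 3.25 ± 0.802. That call passed in 2 of 9 alternatives.

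Ribosome biogenesis genes that follow MYC were the list with the smallest camera p. Of its 28 members, 27 were lower in both siLOL libraries and 15 at least 1.5-fold lower in both (6 with total recovered reads, 10 with median centring, 12 with TMM-like factors), at a median of −0.66 (−0.60 in siLOL 1, −0.72 in siLOL 2). The list passed camera at adjusted p = 8.07e-11, with adjusted p = 0.726 with an estimated correlation, and 0 members passed adjusted over the list alone. MYBBP1A had 384 in siNC and 190 ± 9.81 in siLOL, NOP16 had 248 and 127 ± 1.90, RRP9 had 302 and 153 ± 10.7, and the rRNA methyltransferase gene NOP2 had 219 and 113 ± 19.2. MYC itself had 674 and 439 ± 35.5 (log2 difference −0.62 ± 0.27). Proteins of the cytosolic ribosome did not pass (54 members, median −0.08, adjusted p = 0.124), with medians of 0.17 in siLOL 1 and −0.38 in siLOL 2. Their members RPS15, RPL7A, RPS23 and RPL11 had log2 differences of −0.45 ± 0.26, −0.66 ± 0.35, −0.43 ± 0.31 and 0.49 ± 0.34.

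Genes of DNA replication and G1/S were lower as a group, at a median of −0.57 (−0.66 in siLOL 1, −0.34 in siLOL 2), with 27 of 36 members lower in both libraries and 2 higher in both. Camera gave adjusted p = 3.64e-07, and adjusted p = 0.726 with an estimated correlation, while 0 members passed adjusted over the list alone. The cyclin gene CCNE2 had 65.0 and 24.2 ± 3.56, the licensing factor gene CDC6 had 188 and 94.5 ± 6.86, UNG had 1222 and 674 ± 15.4, and E2F2 had 68.9 and 34.8 ± 7.05. The 3' UTR of CCNE2 holds both siLOL words, and those of UNG and E2F2 hold a siLOL 1 word. CCND1, the cyclin of early G1 and a member of the let-7 target list, had 1541 and 801 ± 114. Mitosis and G2/M genes did not pass (36 members, 9 lower and 9 higher in both, 5 and 15 with total recovered reads, median −0.02, by library −0.15 and 0.16, adjusted p = 0.759). In that list PLK1 (491 and 311 ± 29.4), CCNB1 (751 and 506 ± 6.74) and AURKA (574 and 393 ± 5.25) stood on the lower side, and NDC80 (131 and 197 ± 7.43) on the higher. The proliferation marker MKI67 had 439 in siNC, 320 in siLOL 1 and 548 in siLOL 2.

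The p53 target list was higher as a group, at a median of 0.42 (0.58 in siLOL 1, 0.23 in siLOL 2), with 19 of 28 members higher in both libraries and 4 lower in both. It passed camera at adjusted p = 0.000165, with adjusted p = 0.726 with an estimated correlation, and 0 members passed adjusted over the list alone. Besides PERP, the members named were SPATA18, a factor of mitochondrial quality control (1.97 in siNC, 11.8 in siLOL 1 and 8.19 in siLOL 2), BBC3, which encodes the BH3-only protein PUMA (32.4 and 83.5 ± 24.1), and DDB2, a DNA damage sensor (271 and 554 ± 85.2). The 3' UTR of SPATA18 holds a siLOL 2 word. CDKN1A, the p53 target that encodes the cell cycle inhibitor p21, had 444 in siNC, 1021 in siLOL 1 and 432 in siLOL 2. Regulators of apoptosis did not pass (31 members, 15 higher and 11 lower in both, 18 and 5 with total recovered reads, median 0.13, by library 0.24 and 0.11, adjusted p = 0.303). Of these, CASP7 had 47.8 and 108 ± 10.7, BCL2L2 had 32.6 and 50.5 ± 0.875, and the anti-apoptotic gene BCL2, whose 3' UTR holds both siLOL words, had 173 and 77.2 ± 5.58.

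**Figure D2:**
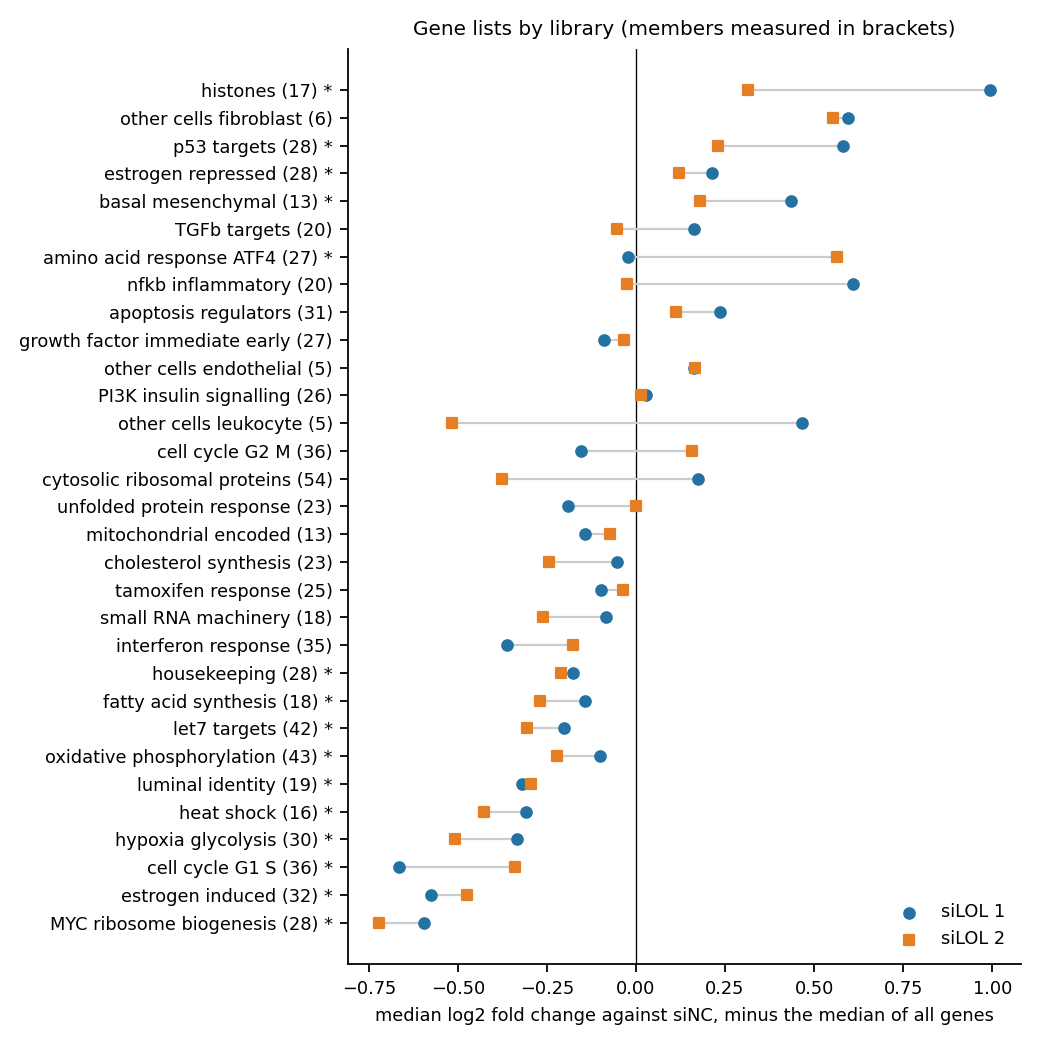
Median log2 difference from siNC of each gene list relative to all genes tested, for siLOL 1 and siLOL 2, with an asterisk at lists with a camera adjusted p under 0.05. Ribosome biogenesis lies at −0.60 and −0.72, and p53 targets lie at 0.58 and 0.23.

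Heat shock genes were lower as a group (median −0.35, by library −0.31 and −0.43), with 13 of 16 members lower in both siLOL libraries and none higher in both. Camera gave adjusted p = 0.00038, and adjusted p = 0.726 with an estimated correlation, while 0 members passed adjusted over the list alone. The chaperone genes HSPB8 (696 and 294 ± 81.5), HSPA8 (3564 and 1865 ± 211), BAG3 (954 and 542 ± 117) and HSPH1 (560 and 312 ± 98.0) were those named. Endoplasmic reticulum stress genes did not pass (23 members, 13 lower and 5 higher in both, 6 and 8 with total recovered reads, median −0.10, with −0.19 in siLOL 1 and near 0 in siLOL 2, adjusted p = 0.197). Besides XBP1, these included DDIT3 (66.2 and 125 ± 16.8), WFS1 (137 and 73.5 ± 12.6) and the chaperone gene HSPA5 (1294 and 807 ± 62.1), whose 3' UTR holds a siLOL 1 word. Targets of ATF4 in amino acid stress passed camera as higher (27 members, 9 higher and 4 lower in both, median 0.20, adjusted p = 0.0488), with adjusted p = 0.815 with an estimated correlation and 0 members adjusted over the list alone. Without siLOL replicate 2 that median was −0.02, against 0.57 in siLOL 2, and the call held in 2 of 9 alternatives. NUPR1 had 68.1 and 213 ± 87.2, with a siLOL 1 word and a siNC word in its 3' UTR. PCK2 had 80.7 and 166 ± 3.68, DDIT4, an inhibitor of mTOR, had 108 and 218 ± 31.0, and ATF5 had 80.7 and 39.0 ± 2.64.

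Hypoxia and glycolysis genes were lower as a group (30 members, 19 lower and 6 higher in both, median −0.36, by library −0.33 and −0.51, camera adjusted p = 0.00913), with adjusted p = 0.726 with an estimated correlation. By voom this list gave adjusted p = 0.495. Among them were LDHA, lactate dehydrogenase (419 and 198 ± 35.7), the glucose transporter gene SLC2A1 (487 and 266 ± 27.0), ALDOC (123 and 64.2 ± 4.72) and PGK1 (606 and 416 ± 3.41), whose 3' UTR holds both siLOL words. Fatty acid synthesis genes were lower (18 members, 10 lower and 5 higher in both, median −0.20, by library −0.14 and −0.27), and so were nuclear genes of the respiratory chain (43 members, 27 lower and 6 higher in both, median −0.20, with −0.10 in siLOL 1 and −0.22 in siLOL 2). With total recovered reads 16 of the respiratory chain genes were lower and 12 higher in both. Both lists passed camera at adjusted p = 0.0488 and gave adjusted p = 0.726 with an estimated correlation, and they held in 1 and 2 of 9 alternatives. The elongase gene ELOVL5 had 262 and 108 ± 18.4, the desaturase gene SCD had 476 and 192 ± 55.9, ELOVL6 had 82.2 and 37.9 ± 9.95, and FADS1 had 57.8 and 32.8 ± 5.99. SCD holds a siLOL 2 word, and ELOVL6 and FADS1 hold a siLOL 1 word. In the respiratory chain, NDUFS2 had 153 and 291 ± 26.4, ATP5G1 had 292 and 176 ± 21.0, ATP5G3 had 299 and 210 ± 0.029, and NDUFV2 had 5.99 and 2.92 ± 0.931. Housekeeping genes were lower as a group (28 members, 20 lower and 4 higher in both, 13 and 6 with total recovered reads, median −0.19, by library −0.18 and −0.21, camera adjusted p = 0.0151, adjusted p = 0.726 with an estimated correlation), and the call was lost in 3 of 9 alternatives. GAPDH had 5861 and 4116 ± 222, SNRPD3, with a siLOL 1 word, had 755 and 467 ± 42.1, and HMBS had 170 and 103 ± 25.6. In all 4 lists 0 members passed adjusted over the list alone. Cholesterol synthesis genes (23 members, median −0.14, by library −0.05 and −0.24, adjusted p = 0.553) and mitochondrially encoded messenger RNAs (13 members, median −0.12, by library −0.14 and −0.07, adjusted p = 0.325) did not pass. PMVK had a log2 difference of 0.99 ± 0.28, DHCR7 of −0.58 ± 0.28, EBP of −0.59 ± 0.29 and NSDHL of −0.57 ± 0.29. MT-ND4, MT-ND4L, MT-ND5 and MT-ND6 had −0.49 ± 0.36, −0.54 ± 0.37, −0.33 ± 0.31 and −0.23 ± 0.30.

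Genes described as let-7 targets were lower as a group (42 members, 22 lower and 6 higher in both, 18 and 9 with total recovered reads, median −0.20, by library −0.20 and −0.31, camera adjusted p = 0.0138), with adjusted p = 0.726 with an estimated correlation and 0 members adjusted over the list alone. The siLOL 2 words lie in the 3' UTRs of 14 of these 42 genes. DICER1, the nuclease that makes microRNAs, had 194 and 70.2 ± 0.127. IRS2, an insulin receptor substrate, had 147 and 61.0 ± 2.24, and BACH1 had 12.1 and 6.20 ± 0.88 with a siLOL 2 word. The let-7 call was lost over genes searched and without a siLOL or siNC word (21 members left, median −0.05, adjusted p = 0.127), without the low-value filter (adjusted p = 0.0771) and by voom (adjusted p = 0.235). Of the let-7 targets fixed as values, HMGA2 and LIN28B lay under the filter. HMGA2 had 0.512 in siNC, 1.52 in siLOL 1 and 0.273 in siLOL 2, and LIN28B had 0.393, 0.186 and 0. CCND1, a member of the list that was fixed as well, had 1541 and 801 ± 114, without a siLOL or siNC word. The microRNA and siRNA machinery did not pass (18 members, 8 lower and 3 higher in both, 6 and 5 with total recovered reads, median −0.18, by library −0.08 and −0.26, adjusted p = 0.111), but 2 members passed adjusted over the list alone, DICER1 and AGO2. AGO2, the slicing Argonaute, had 168 and 65.2 ± 0.88, and the 3' UTRs of DICER1 and AGO2 hold both siLOL words. The member calls were lost without the low-value filter (smallest list-adjusted p 0.0798) and by voom (0.378). XPO5 had 225 and 129 ± 7.55, and RAN, with a siLOL 1 word, had 859 in siNC, 95.7 in siLOL 1 and 566 in siLOL 2.

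Histone genes were higher as a group (17 members, 10 higher and 3 lower in both, median 0.58, camera adjusted p = 0.0138), with adjusted p = 0.726 with an estimated correlation. Their medians were 0.99 in siLOL 1 and 0.31 in siLOL 2, and the call was lost without the low-value filter (adjusted p = 0.0590). Adjusted over the list alone, 2 members passed, HIST1H2BC (16.9 and 46.7 ± 5.30, from 13, 35 and 52 reads) and HIST1H4C, which had 0, about 2 and about 2 reads and so lay under the floor in every library. No member passed so without the low-value filter or at a mean of at least 5. HIST1H1B (9.60 and 2.46 ± 2.03, from about 6, 3 and 1 reads) and HIST1H1E (12.4 and 6.35 ± 0.237, from about 9, 5 and 6) stood on the lower side. Interferon-induced genes did not pass (35 members, 17 lower and 5 higher in both, 15 and 9 with total recovered reads, median −0.19, by library −0.36 and −0.18, adjusted p = 0.0620). OAS1 had 37.4 and 16.8 ± 0.99, OASL had 33.4 and 15.0 ± 0.797, and MX1, with a siLOL 1 word, had 1.01 and 4.49 ± 0.965. IFNL1 had 8.85 and 3.68 ± 0.137, from 7, 3 and 4 reads (read ratio 0.417, 95% exact interval 0.125 to 1.39). NF-κB and inflammatory genes did not pass either (20 members, 8 higher and 4 lower in both, median 0.19, by library 0.61 and −0.02, adjusted p = 0.175). BCL3 had 129 in siNC, 289 in siLOL 1 and 218 in siLOL 2, TRAF1 had 1.51 and 4.38 ± 2.11, NFKBIZ had 24.2 and 15.6 ± 1.94, and LTB, from 1 read in siNC, had a read ratio of 5.43 (95% exact interval 0.82 to 231).

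The remaining lists did not pass camera. Genes of tamoxifen response (25 members, 12 lower and 6 higher in both, 7 and 9 with total recovered reads, median −0.15, by library −0.10 and −0.04, adjusted p = 0.560) included GREB1, which was lower. Higher were CYP2D6 (1.81 and 7.69 ± 0.596), SOX9 (2.48 and 8.04 ± 1.43) and SOX2, with about 1, 5 and 53 reads. In siNC, CYP2D6 rested on about 4 reads and SOX9 on 9. PI3K, insulin and FOXO genes (26 members, median 0.01, by library 0.03 and 0.01, adjusted p = 0.672) included IRS2, ERBB4, SESN3 (3.55 and 8.80 ± 2.67) and AKT1 (190 and 276 ± 4.81). TGF-β targets (20 members, median 0.21, by library 0.16 and −0.05, adjusted p = 0.652) included LTBP2 (3.49 and 13.3 ± 7.55), SMAD7 (76.8 and 47.9 ± 11.1), ANGPTL4 (54.5 and 35.5 ± 5.87) and BAMBI (1148 and 857 ± 53.4). Immediate early genes (27 members, adjusted p = 0.861) had a median of 0.09 (by library −0.09 and −0.03), while their mean and the test pointed down. ETV4 had 7.51 and 1.94 ± 0.742, EGR3 had 7.81 and 2.48 ± 2.62, KLF2 had 20.9 and 40.5 ± 7.98, and FOSL1 had 5.17 and 10.7 ± 2.46. Fibroblast genes (6 members, median 0.57, by library 0.60 and 0.55, adjusted p = 0.168) included COL5A1 (3.78 and 14.9 ± 7.88), COL5A2 (1.21 and 3.75 ± 2.06), COL6A1 (38.1 and 57.9 ± 4.06) and S100A4 (78.2 and 46.7 ± 20.2). Endothelial genes (5 members, median 0.01, by library 0.16 and 0.17, adjusted p = 0.620) included ENG (4.67 and 9.19 ± 0.66), VWF (1.96 and 1.02 ± 0.281), ESAM (3.85 and 5.84 ± 2.26) and EMCN (1.45 and 1.24 ± 0.648). Leukocyte genes (5 members, adjusted p = 0.279) had a median of −0.01 (by library 0.47 and −0.52), with a mean and a test that pointed up. CD8A had 2.38 and 9.66 ± 2.65, CD14 had 1.72 and 0.758 ± 0.464, CD19 had 11.2 and 9.15 ± 5.76, and NKG7 had 0, 8 and 2 reads, with an exact lower limit of 0.936 for the read ratio. Small nuclear and nucleolar RNAs had 0 measured members. A siLOL 1 word also lies in the 3' UTRs of BCL2L2, CAV1, SPARC, RPS23, ATP5G3, FOXA1, PGR, TRAF1, ENG and CD8A, a siLOL 2 word in that of LTBP2, and both in that of EMCN. The 3' UTR of LTBP2 holds a siNC word as well.

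Across the 31 lists tested, 15 passed camera with the preset correlation, 10 lower and 5 higher, and 0 passed with an estimated correlation (adjusted p from 0.726 to 0.938). The latter test rests on the 1 residual degree of freedom, so it could hardly pass. The luminal list had an estimated correlation of −0.053, under the preset 0.01, yet its camera p went from 0.00441 to 0.199. That test therefore cannot tell whether correlation between members accounts for the calls. By fry, 3 lists had an unadjusted p under 0.05: ribosome biogenesis, luminal genes and the tamoxifen list, which camera did not call. Fry rests on the same 1 residual degree of freedom. The lists of ribosome biogenesis, G1/S, estrogen-induced, p53 target, heat shock and luminal genes passed camera with the preset correlation in all 9 alternatives with a test. For the heat shock and luminal lists the highest camera adjusted p was 0.0437. None of these alternatives removed trends with GC content or transcript length. The p-values rest on 1 residual degree of freedom and on a single siNC library assumed to vary like the siLOL pair.

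**Figure D3:**
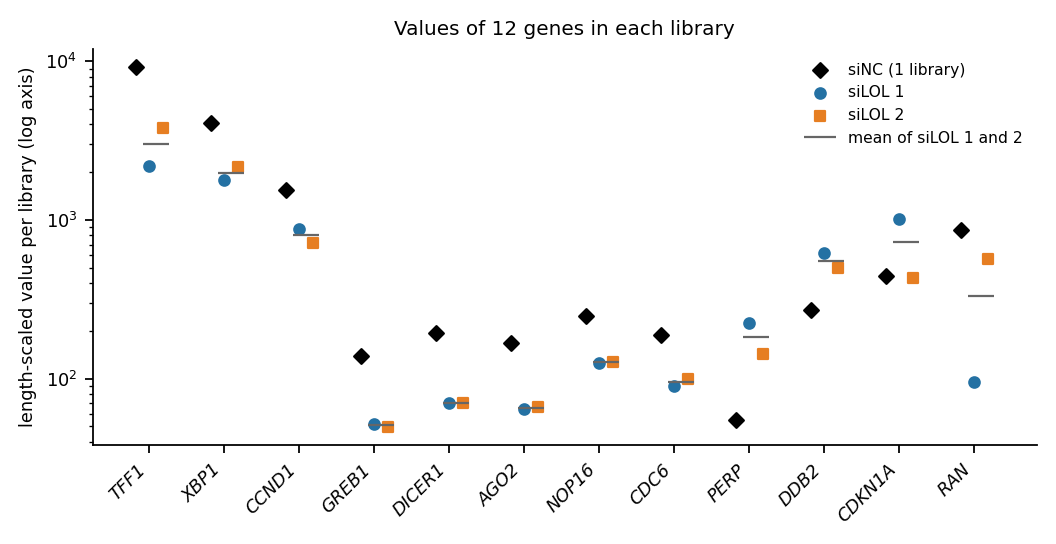
Value of 12 named genes in the siNC, siLOL 1 and siLOL 2 libraries, on a log axis, with 1 point per library. TFF1 lies at 9263, 2184 and 3796, and RAN at 859, 95.7 and 566.

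The comparison of siLOL 1 with siLOL 2 asked how far the knockdown libraries differ. RAN, the GTPase of nuclear transport, had 95.7 in siLOL 1 and 566 in siLOL 2, and TIMP3, an inhibitor of metalloproteinases, had 5.78 and 88.6. HOXB7, a homeobox gene, had 76.8 and 4.79, and CAP1, an actin-binding protein gene, had 348 and 47.3. Such genes numbered 1044 at 2-fold or more, 519 higher in siLOL 1 and 525 higher in siLOL 2. With 1 library each, no test was made of a single gene.

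Among genes with at least 100 reads in either library, the 8 furthest apart on each side were chosen after their values were seen. Lower in siLOL 1 were TIMP3, CCDC28A (31.9 in siNC, 4.79 in siLOL 1, 69.3 in siLOL 2), FAM220A (118, 15.8 and 121), TMEM106C (480, 84.1 and 568), SUMF1 (48.0, 10.3 and 72.5), INPP5A (32.8, 14.1 and 93.2), RAN and ADAM10 (57.6, 12.6 and 77.5). Lower in siLOL 2 were HOXB7, FBXO27 (211, 365 and 49.1), CAP1, FAM127C (204, 246 and 41.7), IDH1 (170, 219 and 39.6), RAB31 (36.1, 28.8 and 4.64), TMEM30B (145, 223 and 42.5) and CREBL2 (54.9, 70.2 and 13.8).

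The fold changes of both siLOL libraries against the shared siNC library correlated across genes at r = 0.595 (rho = 0.591), where libraries simulated without an effect gave 0.499 (range 0.483 to 0.520). That simulation gave siNC the spread of the siLOL pair and drew genes independently. A siNC library of larger spread would give a higher r without an effect, so the gap does not show a shared effect. Genes are not independent replicates. Of 16384 words of 7 bases, GTGGTGA marked the genes that stood lowest in siLOL 1 (1086 genes, mean log2 difference from others −0.27, z = −15.6), and ACTACCT those in siLOL 2 (660 genes, −0.30, z = −13.9). The lowest z in 100 shuffles was −4.80 and −4.75. Of genes at least 2-fold lower in siLOL 1 than in siLOL 2, 45.4% hold a siLOL 1 word and 6.90% a siLOL 2 word, against 22% and 10.3% of all 12271 genes searched. For genes at least 2-fold lower in siLOL 2 the shares were 14.4% and 27.9%. The words were picked from the same fold changes, so these shares are no separate support for them. Genes at least 2-fold lower in both libraries held the siLOL 1 words in 26.9% and the siLOL 2 words in 16.6%. Genes with the siNC word TCGGAGA were higher in both siLOL libraries (192 genes, z = 6.07 and 8.31, beyond every shuffle), with z = −1.97 between siLOL 1 and siLOL 2. Of the 1044 genes at least 2-fold apart, 994 had a searched 3' UTR, and 562 of these hold no siLOL or siNC word. Over the 8629 genes searched and without these words r was 0.637, but no simulation was run for this set. The words left out were picked from the same fold changes.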

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

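The tests with scaling to total recovered reads, with voom and over word-free genes (3' UTR searched and none of the 6 words) were chosen only after the results were seen. No gene passed limma at an adjusted p under 0.05 under any of the 9 alternatives with a test. The smallest adjusted p came nearest over word-free genes (0.0590, 8629 genes, 1055 at an unadjusted p under 0.05) and was 0.549 as reported, with 1111, and 0.590 by voom, with 638. The 337 genes at least 2-fold higher in both siLOL libraries became 554 with a pseudocount of 0.1, 208 at a mean of at least 5, 536 with total recovered reads, 1056 at 1.5-fold and 16 at 4-fold. Leaving out one siLOL library gave 686 to 764, since only the other then had to pass. The 155 genes at least 2-fold lower in both became 97 with total recovered reads, 91 over word-free genes (of 145 searched), 83 by voom, 753 at 1.5-fold and 5 at 4-fold, and 597 to 671 with a library left out. Apart from the fold thresholds and the smaller gene sets, the cause was not tested.

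Of 31 lists, 15 passed camera as reported, 9 without the low-value filter and 6 by voom. Over the lists called and the alternatives with a test, 39 of 134 calls were lost, and 0 of the 15 lists turned direction. The median of the ATF4 list was −0.0226 without siLOL replicate 2 and 0.57 without siLOL replicate 1, and the cause was not tested. Counts adjusted over the list alone also moved: over word-free genes 5 members passed in the ribosome biogenesis and estrogen-induced lists and 4 in the p53, heat shock and ATF4 lists, where 0 passed as reported. The words were picked from these fold changes and mark the genes furthest apart between siLOL 1 and siLOL 2, the only replicate spread of the fit. Leaving out their genes lowers that spread by selection (prior degrees of freedom 11.9, against 5.78 as reported). The smallest adjusted p and member counts over word-free genes can follow from this choice. Interferon-induced genes, not called, were the 1 list that passed under an alternative (adjusted p from 0.0279 to 0.235 over its alternatives). Of 146 named genes, 142 kept the sign of their difference in every alternative. CDKN1A, MKI67, EMCN and CD19 did not. Between siLOL 1 and siLOL 2, the 1044 genes at least 2-fold apart became 562 over word-free genes, against 994 over all genes searched. The correlation of 0.595 became 0.620 with a pseudocount of 0.1 and 0.637 over word-free genes, and neither was set beside a simulation of its own.

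No paired analysis was possible because the groups share fewer than 2 replicate numbers. The planned count-based alternatives were not run because the file holds no counts. Depth limits genes of few reads: in siNC a gene of 1 kb at a value of 3.25 rests on 3 reads.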

Other observations

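The descriptions of zinc finger genes and HMOX1, the tests of counting error, of a different siRNA seed match and of GC content and UTR length between the siLOL libraries, and the test of let-7 targets in siLOL 1 were chosen only after the results were seen. Genes named ZNF and a number, most of which encode DNA-binding zinc finger proteins, stood higher in siLOL. Of 383 such genes tested, 237 were higher in both siLOL libraries, and their medians relative to all genes were 0.38 in siLOL 1 and 0.44 in siLOL 2. Over 236 of these genes searched and without a siLOL or siNC word the medians were 0.36 and 0.41. ZNF468 had 24.0 in siNC and 75.9 ± 4.51 (SD, n = 2) in siLOL, ZNF83 had 24.3 and 64.8 ± 13.3, ZNF76 had 36.7 and 83.1 ± 3.85, and ZNF721 had 118 reads in siNC, 283 in siLOL 1 and 357 in siLOL 2. The 3' UTR of ZNF468 holds a siLOL 1 word.

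HMOX1, the heme oxygenase induced by oxidative stress, had 284 in siNC and 989 ± 66.9 in siLOL (log2 difference 1.79 ± 0.26, adjusted p = 0.549). It rested on 631, 2211 and 3078 reads, and its 3' UTR holds no siLOL or siNC word.

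Genes differed between siLOL 1 and siLOL 2. Between these libraries the words of the most extreme genes had z of −18.4 and 14.8, beyond the shuffles (−4.82 and 5.21), which argues against counting error for the genes that hold them, since it does not follow sequence. Genes with GTGGTGA were lowest in siLOL 1 (z = −15.6) and genes with ACTACCT in siLOL 2 (z = −13.9), beyond every shuffle, while each library's words had z from −0.818 to 1.02 in the other. A candidate explanation is that the libraries received siRNAs of different seed, and regression on GC content, UTR length and level left z at −15.5 and −14.9, which argues against those trends. CCDC28A, TMEM106C and CAP1 hold none of the words, 562 genes without them were still at least 2-fold apart, and for these, variation between cultures and a different depth of knockdown stay open as untested.

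The let-7 target list was lower in the siLOL libraries. With more free let-7 after the knockdown, genes with the let-7 word CTACCTC and no siLOL or siNC word were predicted to be lower in siLOL 1. The 387 such genes were not, and differed from other genes by 0.0266 ± 0.0273 there (SE, log2, z = 0.973). In siLOL 2 they differed by −0.06 (z = −2.25). Over all 952 genes with CTACCTC, some with a siLOL 2 word, z in siLOL 2 was −3.265, the 26th lowest of the words. That z lies inside the range of the shuffles, whose lowest was −4.747. The level of LOL was not seen in either library, so this explanation stays open. The siLOL 2 words, which share CTACCT with the let-7 word, lie in 33.3% of the list's genes and in 10.3% of all genes searched. The 14 members with them had a median of −0.90 ± 0.29 in siLOL 2, and the 28 without had −0.17 ± 0.11 relative to genes without, while in siLOL 1 the 32 members without a siLOL 1 word had −0.17 ± 0.19. Since both medians lie within 2 standard errors of 0, a part beyond genes that hold these words cannot be told apart from none in either library, and whether the words are siRNA sites was not tested against a siRNA sequence.

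Ribosome biogenesis, G1/S and estrogen-induced genes were lower in both siLOL libraries. Over members searched and without a siLOL or siNC word their medians were −0.67 ± 0.08, −0.60 ± 0.09 and −0.69 ± 0.14 relative to such genes. This argues against sites of the 6 words in the 3' UTRs searched as the cause, and related words outside the 6 were not left out. After regression on GC content, transcript length and level the medians were −0.45 ± 0.07, −0.44 ± 0.07 and −0.56 ± 0.11, which argues against those trends as the whole cause. With 1 siNC library, an siNC library that stands apart cannot be told apart from an effect of the knockdown, and genes with the siNC word TCGGAGA stood lower in siNC than in both siLOL libraries (z = 6.07 and 8.31 for siLOL against siNC). ESR1 and CCNE2 hold both siLOL words, so if the words are siRNA sites, those in a regulator could act on other genes, which was not tested and stays open beside loss of LOL.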
